A study of Mus musculus with 3 samples.

How the data were processed

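Messenger RNA of sorted CD45+CD11b+Siglec-F+ cells was measured with 10x Chromium 3' v3 libraries on an Illumina HiSeq instrument, in 3 libraries of pooled mice: lung OVA+SIA, synovium OVA+SIA and synovium SIA. The deposited tables hold whole UMI counts per gene and cell, with no normalisation, since cell totals are not equal. The submitters' notes name Cell Ranger 3.0.1, Seurat 3.1.0, R 3.6.1 and the mm10 genome. The settings of their filters on cells and genes are not given in the sources used here. In the tables, the lowest cell totals were 504, 498 and 500 UMIs, the lowest numbers of detected genes 308, 327 and 322, and the highest shares of mitochondrial UMIs 20.0, 19.1 and 18.3% (lung OVA+SIA, synovium OVA+SIA and synovium SIA). The tables list 12472, 11631 and 11932 genes, of 13440 over all 3 and 10729 shared by all. A gene that a table did not list was taken as 0 counts there, and no fold of such a gene by itself is given. List medians and numbers of members past 2-fold do include such genes, at a floor of 3 counts. Positions come from GENCODE M21, in which 13299 of the symbols name 1 gene.

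The cell classes, gene lists, rule for naming genes, tests and first set of alternatives were fixed before the data were examined. Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, which removed no cell. Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes, 20 principal components and 15 neighbours were used for Leiden clustering at resolution 0.5, with the libraries together and without integration. The tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A cluster took the name of a class, with "-like" added, when at least 3 markers of that class were raised at least 2-fold over the other cells and present in at least 10% of its cells. It stayed unnamed when its 10 leading genes held as many or more markers of another class, or when another class had nearly as many raised markers. This last condition was relaxed between related phagocyte classes after seeing the data. Scrublet called 1 doublet in the lung library and 0 in both synovium libraries, and doublets were kept.

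For each comparison, UMIs were summed over the cells of a class in each library and given as counts per 1000000 UMIs (CPM) of that sum. Since each group had 1 library, no p-value, standard error or number of changed genes was computed. Levels have exact Poisson intervals, ratios exact conditional binomial intervals, and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. Where a listed gene had 0 counts in a class, the ratio was taken against a floor of 3 counts and is only an approximate bound. For shares of cells with a UMI, each cell was also thinned at random to 500 UMIs, and shallower cells were left out.

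Of the 17 gene lists compared, 5 were set as primary: regulatory and pro-resolving factors, inflammatory cytokines and chemokines, eosinophil granule proteins, and resident-type and inflammatory-type eosinophil markers. Another 18 lists held cell type markers and named the clusters. The granule protein genes other than Prg3 and Ear10 are also among the eosinophil markers. For each list the members with at least 20 UMIs over the libraries compared were used, and the median log2 ratio is given with its 95% range over 1000 Poisson redraws of the counts. Its percentile among 10000 random lists of the same size, matched on expression, describes these libraries and is no test. Genes named in the text were those with at least 50 UMIs, a UMI in at least 5% of cells of the library where they were higher, the same direction over all cells and a ratio of at least 2-fold. The 12 highest and 12 lowest were taken by the interval bound nearest to 0, leaving out mitochondrial and ribosomal protein genes and unnamed transcripts; up to 4 members of each list and the sorted markers were added. Il10, Il1rn between the joints, Cd80 in the synovium, Alox15, and list members beyond these were chosen after their values were seen. Some genes that the rule names are not reported here.

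The comparisons were synovium OVA+SIA against synovium SIA and lung OVA+SIA against synovium OVA+SIA, both meant for eosinophil-like cells. The plan fell back to all cells where a library kept under 30 eosinophil-like cells, which was the case for lung. A comparison of eosinophil-like cells named within each library clustered alone was then added after seeing the data. The pair of lung OVA+SIA and synovium SIA differs in tissue and treatment and is only described, as are Spearman correlations across genes.

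The intervals and list medians were tested on simulated data with 200 genes set to 2-fold or 4-fold changes. The simulated sums were drawn from Poisson distributions, the model the intervals assume, without variation between cells. This checks the calculation and cannot show how well the intervals hold for these cells. For eosinophil-like cells of the joints the interval held the true ratio for 96.6% of 3233 unchanged genes and lay on the true side of 0 for 83.3% of 2-fold and 100% of 4-fold genes. For all lung and synovium cells these were 95.8, 91.8 and 99.0%, and for lung eosinophil-like cells 98.0, 57.4 and 94.3%. Of 50 lists of 12 unchanged genes, 48, 49 and 48 fell inside the central 95% of random lists in these comparisons; of 50 lists raised 2-fold, 50, 50 and 49 lay above it.

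Alternatives tried were no cell filter; at least 500 genes and at most 10% mitochondrial UMIs; Leiden resolution 1.0; each library clustered alone; doublets left out; all cells; equal weight per cell; scaling by the median ratio over genes or by a total without mitochondrial, ribosomal protein and the 50 most abundant genes; thinning; and list members with at least 100 UMIs or at least 1. Single clusters of the eosinophil-like and neutrophil-like cells were added after seeing the data.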

Results

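Sorted CD11b+Siglec-F+ cells of mice were profiled by single-cell RNA sequencing to ask how eosinophils of the arthritic joint differ when the animals also have allergic airway inflammation, and how they differ from eosinophils of the inflamed lung. Balb/c mice aged 6 weeks received 150 µl of serum from K/BxN mice, whose autoantibodies set off joint inflammation (serum-induced arthritis, SIA). Some had ovalbumin (OVA) asthma as well, made by sensitisation with 100 µg of the protein and intranasal challenges with 50 µg. On day 7 after serum, cells positive for CD45 (leukocytes), CD11b (a myeloid integrin) and Siglec-F (a lectin of eosinophils that alveolar macrophages also carry) were sorted, and 8000 cells were loaded per library. Each of the 3 groups had 1 library: lung OVA+SIA pooled 3 mice, synovium OVA+SIA pooled 16 hind ankle joints of 8 mice, and synovium SIA pooled 24 joints of 12 mice. With 1 library per group there were no replicates, and every interval given here is a 95% interval for counting error alone. It does not cover differences between mice or between libraries.

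The lung OVA+SIA library held 538 cells with 6501893 unique molecular identifiers (UMIs), a median of 6517.5 per cell. Synovium OVA+SIA held 478 cells with 2164753 UMIs and a median of 1286.5. Synovium SIA held 375 cells with 2463322 UMIs and a median of 2142. The shallowest cells had 504, 498 and 500 UMIs, so each share of cells is a share of the sorted gate above a floor of about 500 UMIs.

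Among the sorted cells, eosinophil-like cells were the largest class from the joint of mice with asthma. Neutrophil-like cells were the largest from the joint of mice with arthritis alone. The eosinophil-like share was 60.7% of synovium OVA+SIA (290 cells, exact Clopper-Pearson interval 56.1 to 65.1%) and 27.5% of synovium SIA (103 cells, 23.0 to 32.3%). The neutrophil-like share was 22.6% (18.9 to 26.6%) against 45.1% (40.0 to 50.3%), and the monocyte-like share 10.7% (8.05 to 13.8%) against 16.0% (12.4 to 20.1%). The lung library had another make-up: alveolar macrophage-like cells were 32.2% of it (173 cells, 28.2 to 36.3%), against 0 of 478 and 0 of 375 cells in the synovium. An unnamed cluster of 283 cells, 259 of them from the lung, carried complement C1q and MHC class II transcripts. The monocyte-like share of the lung was 4.46% (2.88 to 6.57%) and its neutrophil-like share 2.42% (1.29 to 4.10%). Only 3 lung cells (0.558%, 0.115 to 1.62%) were eosinophil-like when the libraries were clustered together, but 49 cells (9.11%, 6.81 to 11.9%) were when the lung library was clustered alone, an alternative planned for the shares. The other myeloid classes depended on the clustering as well: with each library alone, alveolar macrophage-like cells were 15.99% of the lung library and monocyte-like cells 18.96% of it and 0% of both synovium libraries. At Leiden resolution 1.0, monocyte-like cells were 6.69% of synovium OVA+SIA and 11.7% of synovium SIA.

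**Figure D1:**
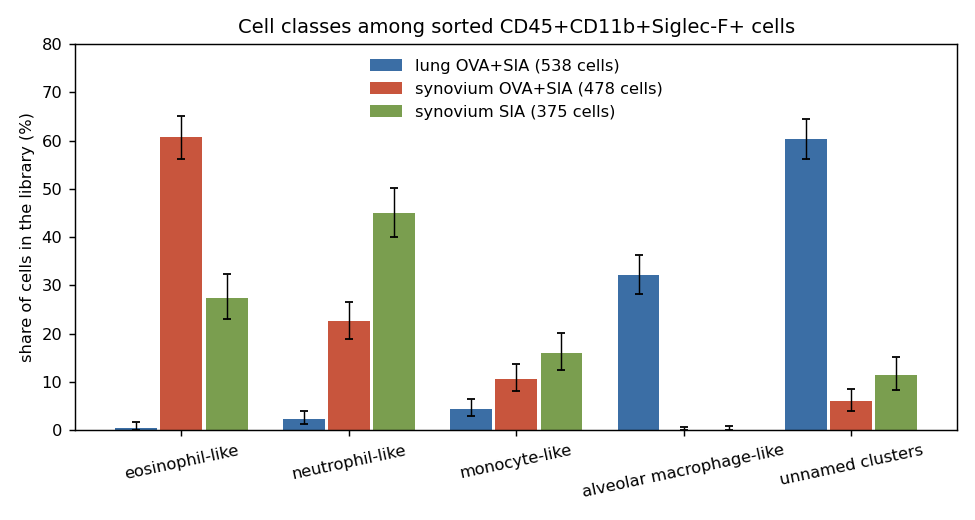
Share of cells (%) in each cell class for lung OVA+SIA (538 cells), synovium OVA+SIA (478 cells) and synovium SIA (375 cells), as bars with exact 95% Clopper-Pearson intervals. Eosinophil-like cells reach 60.7% in synovium OVA+SIA and 27.5% in synovium SIA, and alveolar macrophage-like cells appear in the lung alone.

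Because granule protein genes helped define an eosinophil-like cluster and also differed between the joints, the clustering was repeated without them. The shares were then 60.9% (56.3 to 65.3%) in synovium OVA+SIA and 27.5% (23.0 to 32.3%) in synovium SIA. The clusters were still named with the full marker list, which holds Epx, Prg2, Ear1, Ear2 and Ear6. The repeat therefore covers the grouping of cells and not the naming of clusters. In the main clustering, the cluster led by Ccr3 had 4 raised markers, none a granule gene. It was 39.7% of synovium OVA+SIA and 23.7% of synovium SIA. The gate required Siglec-F protein. Its transcript was found in a smaller share of neutrophil-like than of eosinophil-like cells, but on few cells and without a test of the difference. After every cell was thinned to 500 UMIs, a Siglecf UMI was found in 2.78% of neutrophil-like cells of synovium OVA+SIA and 5.33% of synovium SIA, against 7.27% and 7.77% of eosinophil-like cells. Before thinning these shares were 8.33% and 12.4% in neutrophil-like cells, with median depths of 2975.5 and 2376 UMIs, and 14.8% and 17.5% in eosinophil-like cells, with medians of 932 and 922 UMIs. Thinning left out 1 eosinophil-like cell of synovium OVA+SIA.

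Between the joints, eosinophil-like cells from mice with asthma and arthritis carried more transcript of the cytotoxic granule proteins than those from mice with arthritis alone. They carried less of the chemokine gene Ccl9, of the myeloid growth factor gene Csf1 and of receptor chains for GM-CSF. The sums covered 290 cells with 351385 UMIs in synovium OVA+SIA and 103 cells with 118454 UMIs in synovium SIA. Prg2, the gene of major basic protein (chromosome 2, 84980461 to 84983632, mm10), stood at 21726 counts per 1000000 UMIs (CPM) against 8383, a log2 ratio of 1.37 (1.28 to 1.47). Epx, the gene of eosinophil peroxidase (chromosome 11, 87864000 to 87875536), stood at 714 against 160.4 CPM, a log2 ratio of 2.15 (1.48 to 2.91). The eosinophil-associated ribonuclease genes followed: Ear1 at 2023 against 439 CPM (log2 2.20, 1.80 to 2.64), Ear2 with a log2 ratio of 1.91 and Ear6 with 1.73. Of the 6 measured granule protein genes, 5 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.82 (1.49 to 2.07 when the counts were redrawn) at percentile 100 of random lists. Over all cells of the libraries that median was 3.23. A Prg2 UMI was present in 52.1% of the cells against 27.2%, and in 38.4% against 17.5% after thinning to 500 UMIs. In neutrophil-like cells, which should lack the gene, those thinned shares were 6.48% and 4.14%, with median depths of 2975.5 and 2376 UMIs before thinning. With every cell thinned the Prg2 log2 ratio was 0.58 and that of Epx 0.997, and with equal weight for each cell they were 0.62 and 1.31.

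The class was made of 2 clusters in different proportion. Cluster 3, led by Ccr3 (the eotaxin receptor) and Fgfr1, gave 190 cells in synovium OVA+SIA and 89 in synovium SIA. Cluster 9, led by the granule genes, gave 100 and 14. Within cluster 3 alone, a choice made after seeing the data, the log2 ratios were 0.71 for Prg2, 0.59 for Ear2, 1.404 for Ear1 and 1.54 for Ear6, and Epx had too few counts for a ratio. Other genes higher in synovium OVA+SIA were those of the linker histone Hist1h1c (891 against 355 CPM, log2 1.33, 0.86 to 1.83), the respiratory chain subunit Ndufb7 (1.87, 0.83 to 3.13), the nucleoside diphosphate kinase Nme1, the lysosomal sulfatase Arsb, the fucosyltransferase Fut8 and Cox7a2l, with log2 ratios from 1.29 to 2.10. H2afx, a histone variant used in DNA repair, had 57 counts against 1 (log2 4.26, 1.73 to 9.59). Within cluster 3 alone its log2 ratio was -0.26, and 1.32 with cells thinned. Markers of dividing cells went with these histone genes: 4 of 5 measured were at least 2-fold higher, with a median log2 ratio of 2.10 (1.07 to 2.89).

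Among the genes lower in synovium OVA+SIA, Ccl9 (chromosome 11, 83572919 to 83578636) stood at 401 against 1629 CPM, a log2 ratio of -2.02 (-2.35 to -1.70). Csf1 stood at 216 against 616 CPM (-1.51, -1.99 to -1.03). Both chains of the GM-CSF receptor were lower, Csf2ra at 96.8 against 287 CPM (-1.57, -2.30 to -0.84) and Csf2rb, the chain shared with the IL-3 and IL-5 receptors, at 228 against 515 CPM (-1.18, -1.68 to -0.67). With equal weight for each cell the Csf2rb log2 ratio was -0.42. Retnla, an alternative activation gene, had the lowest log2 ratio (-2.57, -3.13 to -2.03), but its UMIs lay in 2.07% of cells against 5.83%. Notch1 and its partner Rbpj, the transcriptional regulators Id2 and Fos, the matrix glycoprotein gene Thbs1, and Tiparp and Gcnt1 were also lower, with log2 ratios from -1.57 to -1.03. The genes of the sorted surface markers differed less: Siglecf by -0.43 (-1.15 to 0.33), Itgam (CD11b) by 0.09 (-0.20 to 0.38) and Ptprc (CD45) by -0.27 (-0.54 to 0.01).

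**Figure D2:**
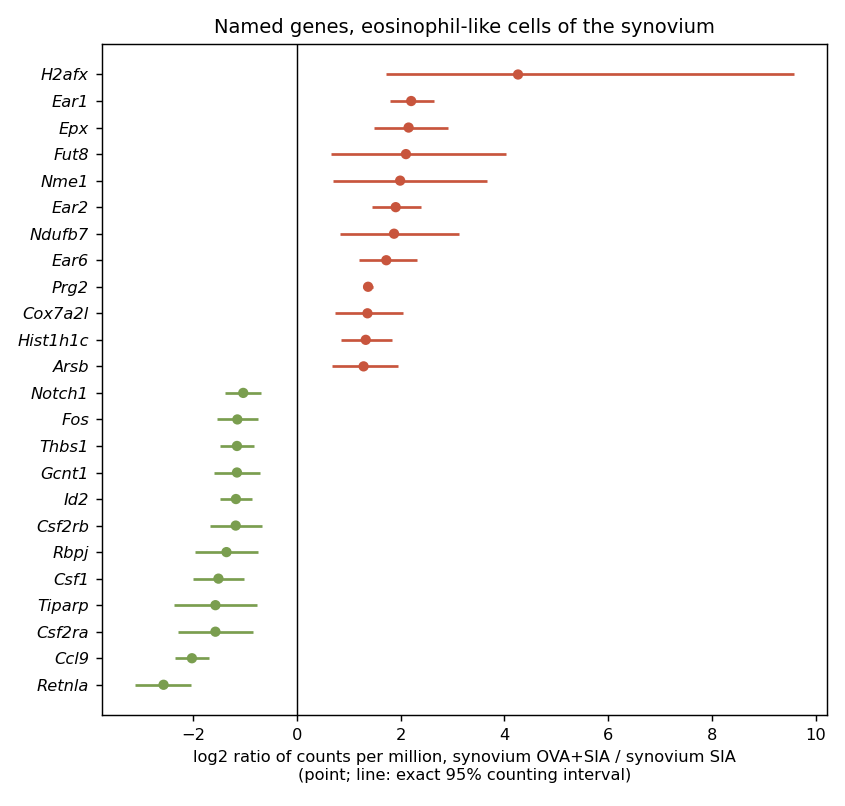
Log2 ratio of CPM, synovium OVA+SIA over synovium SIA, for the 12 genes named each way in eosinophil-like cells (290 and 103 cells); points are ratios and lines exact 95% counting intervals. Ear1, Epx, Ear2, Prg2 and Ear6 lie between 1.37 and 2.20, and Retnla and Ccl9 lie at -2.57 and -2.02.

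Immediate early and stress genes were lower as a group in eosinophil-like cells of synovium OVA+SIA. The median log2 ratio of 18 measured members was -0.54 (-0.63 to -0.36), at percentile 0.03 of random lists, although only 2 members were at least 2-fold lower and 0 higher; Fosb differed by -1.11 and the phosphatase gene Dusp1 by -0.83. The 15 adhesion and trafficking receptors had a median of -0.48 (-0.60 to -0.15, percentile 0.675) with 0 members past 2-fold; the chemokine receptor Cxcr4 differed by -0.88 and the complement receptor C3ar1 by -0.90. Glycolysis and hypoxia genes had a median of 0.32 over 16 members (-0.0046 to 0.55, percentile 98.9), a range that held 0, and 0 past 2-fold. Of these, Gpi1 differed by 0.74 and Pgk1 by 0.70. Within cluster 3 alone the medians were -0.25 for immediate early genes and -0.0157 for adhesion receptors.

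Regulatory and pro-resolving factors leaned neither way as a group between the joints. Of 9 measured, 0 were at least 2-fold higher and 1, Retnla, lower, with a median of 0.02 (-0.29 to 0.13, percentile 75.02). Il1rn, the gene of the IL-1 receptor antagonist, stood at 982 against 1266 CPM (log2 -0.37, -0.65 to -0.08), and Il4 at 205 against 338 CPM (-0.72, -1.30 to -0.13). Il10, of the same list, had 1 count against 0, too few for a ratio. Of 12 inflammatory cytokines and chemokines, 1 was at least 2-fold higher (Il6, 19 counts against 1, log2 2.68, 0.03 to 8.06) and 3 lower (Ccl9, Csf1 and Ccl4), with a median of -0.31 (-0.55 to 0.03, percentile 4.50). The 11 inflammatory-type eosinophil markers had a median of -0.43 (-0.68 to -0.11, percentile 5.69), with 2 at least 2-fold lower, Csf2rb and its homologue Csf2rb2. Within cluster 3 alone it was -0.029. Over all cells of the libraries that median was 0.12, of the opposite sign. The 5 measured resident-type markers had a median of 0.17 (-0.39 to 0.64), with 0 past 2-fold.

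In eosinophil-like cells of the joints, IL-5 and beta common receptor signalling had 1 of 11 members at least 2-fold higher, the feedback inhibitor Socs2 (1.40), and 4 lower, Csf2ra, Csf2rb, Csf2rb2 and Id2, with a median of -0.18, and -0.035 within cluster 3 alone. Among the other lists the median was -0.54 over 4 IL-4 and IL-13 response genes, -0.36 over 12 tissue repair factors, -0.20 over 17 NF-kappaB targets and -0.07 over 3 interferon response genes. It was 0.02 over 9 eicosanoid genes, -0.04 over 13 cell death and survival genes and -0.08 over 12 mitochondrially encoded transcripts. For MHC class II antigen presentation only Cd80 was measured (-0.05). Neutrophil markers were also somewhat higher in eosinophil-like cells of synovium OVA+SIA, with 2 of 9 at least 2-fold higher and a median of 0.36 (0.22 to 0.88).

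**Figure D3:**
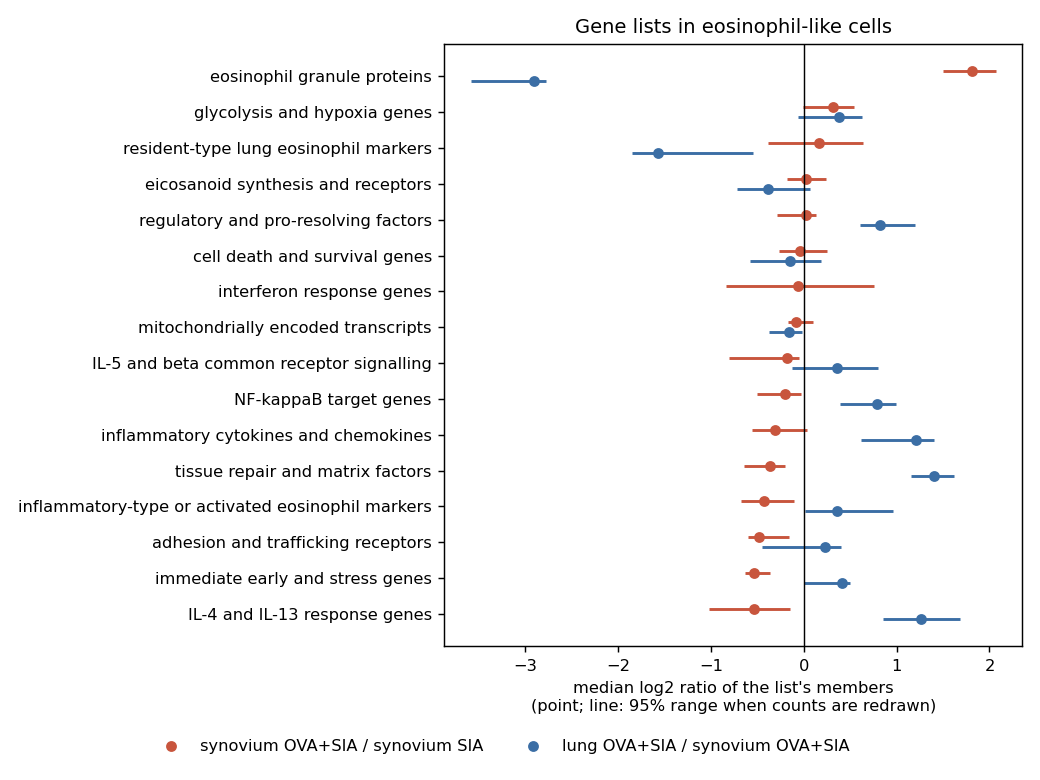
Median log2 ratio of the measured members of each gene list with at least 3 measured members in eosinophil-like cells, for synovium OVA+SIA over synovium SIA and for lung OVA+SIA over synovium OVA+SIA; lines are 95% ranges when the counts are redrawn. Granule proteins lie at 1.82 between the joints and at -2.90 between the tissues.

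The comparison of lung with synovium, both from mice with OVA+SIA, asked how the same disease setting looks in the airway and in the joint. Too few lung cells were eosinophil-like when the libraries were clustered together, so the planned fallback to all sorted cells was used. The lung library was higher in macrophage genes and the synovium library in neutrophil and granule genes. Mmp12, the macrophage elastase gene, stood at 7065 CPM in the lung, and Plet1 and Atp6v0d2, alveolar macrophage markers, at 625 and 738 CPM; the synovium table did not list these genes. Chil3, a chitinase-like protein of alveolar macrophages, stood at 50681 against 422 CPM (log2 6.91, 6.82 to 7.00), and the immunoglobulin kappa gene Igkc at 2138 against 14.3 CPM (7.22, 6.72 to 7.78, but 4.80 after thinning and 5.56 with equal weight per cell). The other genes named as higher in the lung were Ccl8, Jchain, Ccl17, Ch25h, Rnase2a, Ighg1 and Car4. Synovium was higher in genes of neutrophil granules, with Ngp at 0.923 CPM in lung against 7692 and Ltf at 3 counts against 4906 (log2 -12.26, -14.54 to -10.71, but -8.72 with equal weight per cell and -7.12 after thinning). Camp, Mpo, Elane, Ms4a3 and the cartilage collagen gene Col2a1 were not listed in the lung table and stood at 5009, 1866, 1237, 254 and 1028 CPM in the synovium. The lubricin gene Prg4 (-10.46), the fibrillar collagen genes Col3a1 (-9.59) and Col1a1 (-8.68) and the protease gene Prtn3 (-9.15) were lower in the lung as well. With equal weight for each cell these 4 log2 ratios were nearer 0, at -5.425, -4.997, -4.06 and -7.19. Thinning moved the ratios of all 24 genes ranked in this comparison beyond their intervals. For genes with 0 counts in 1 library such a move says little, since the floor of 3 counts stands for a higher level in the smaller thinned totals. Sorted marker genes were lower in the lung too, with Siglecf at 14.9 against 38.8 CPM (-1.38, -1.82 to -0.94), Itgam at 111 against 563 and Ptprc at 439 against 674.

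By list, all 10 alveolar macrophage markers were at least 2-fold higher in the lung library, but 7 of them were not listed in the synovium and were taken at a floor of 3 counts, so the median log2 ratio of 6.22 rests on that floor. All 14 neutrophil markers were lower (median -4.75, with Camp at the floor). IL-4 and IL-13 response genes had 11 of 16 members at least 2-fold higher and 1 lower, with a median of 3.05 (2.75 to 3.40, percentile 100, with 3 members at the floor); the type 2 chemokine gene Ccl24 stood at 947 against 10.6 CPM. MHC class II antigen presentation had 9 of 11 higher and a median of 2.42 (2.18 to 2.495). Granule proteins had 5 of 6 lower and a median of -6.98 (-7.53 to -6.45), with Ear6 and Prg3 not listed in the lung and taken at the floor. With cells thinned, which gives deep macrophages no more weight than shallow granulocytes, that median was -3.67. The floor also stands for a higher level in the thinned totals, and the 2 effects were not separated. Ear2 went the other way (log2 3.25), and alveolar macrophages also express it. Of 18 regulatory factors 8 were higher and 4 lower, with a median of 0.48, which became 1.10 after thinning. Of 19 inflammatory cytokines and chemokines 7 were higher and 3 lower (median -0.12, with -0.38 after thinning and 0.26 among members with at least 100 UMIs). Resident-type markers had a median of -1.25 over 7 genes and inflammatory-type markers -0.09 over 13, which became -1.17 with equal weight per cell and 0.41 among members with at least 100 UMIs. Glycolysis and hypoxia genes (10 of 23 lower, median -0.63) and adhesion receptors (9 of 19 lower, -0.87) were lower in the lung.

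The remaining lists had medians from -0.34 to 0.41 between all lung and all synovium cells. They were -0.34 for interferon response genes, -0.31 for NF-kappaB targets, 0.01 for immediate early genes, -0.08 for eicosanoid genes, 0.08 for tissue repair factors, 0.02 for cell death genes and 0.33 for mitochondrially encoded transcripts. IL-5 and beta common receptor signalling had 0.41, which turned to -0.19 after thinning. These sums set a lung library with 0.558% eosinophil-like and 2.42% neutrophil-like cells against a synovium library with 60.7% and 22.6%, so they describe the 2 sorted populations and not a cell type.

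A comparison of eosinophil-like cells alone became possible when each library was clustered by itself, a choice made after seeing the data. Which cells these are is less certain in the lung: that cluster met the naming rule with 3 raised markers, the minimum (Ccr3, Prg2 and Alox15), and with the libraries clustered together 44 of these cells lay in a cluster left unnamed with 2 (Ccr3 and Alox15), apart from the synovial clusters 3 and 9. The comparison set 49 lung cells (40941 UMIs, median 729 per cell) against 292 synovium OVA+SIA cells (352983 UMIs, median 932). Lung eosinophil-like cells carried far more Il1rn (chromosome 2, 24336853 to 24351494), at 14777 against 986 CPM, a log2 ratio of 3.91 (3.71 to 4.10). An Il1rn UMI was found in 95.9% of them against 39.7%, and in 95.9% against 29.9% after thinning to 500 UMIs. The other lung cells had 309 CPM, and the thinned share in alveolar macrophage-like cells, with a median of 13484 UMIs before thinning, was 14.5%. Il1rn was also among the leading genes of that cluster of 44 lung cells and 1 synovial cell. These are largely the same cells and counts, so this is no separate evidence. Retnla stood at 3175 against 125 CPM (4.67, 4.17 to 5.20, with 3.97 after thinning) and Chil3 at 4690 CPM against 3 counts (9.11, 7.54 to 11.40), but the other lung cells held 1584 and 50973 CPM of these genes. Further genes higher in the lung cells were Vegfa, an angiogenic factor (2.39), the tetraspanin Cd9 (1.81, 1.44 to 2.17), Nfkb1 (1.72, 1.33 to 2.10), the nuclear receptor Nr4a1 (1.57, 1.04 to 2.07, but 0.79 among cells with at least 500 genes and at most 10% mitochondrial UMIs), the lysosomal genes Ctsb and Psap (2.56 and 1.64), Ell2 and Samd4b.

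Granule transcripts were lower in the lung cells, although a Prg2 UMI was present in 61.2% of them against 52.1% of the synovial cells. Prg2 stood at 1905 against 21630 CPM (-3.51, -3.85 to -3.18, but -2.69 after thinning and -2.79 with equal weight per cell) and Ear1 at 2 counts against 711 (-5.37, -8.41 to -3.51), while Ear6 and Prg3, at 861 and 348 CPM in the synovium, were not listed in the lung. All 6 measured granule genes were at least 2-fold lower, with a median of -2.90 (-3.59 to -2.77) with Ear6 and Prg3 at the floor, and of -2.23 after thinning and -2.43 with equal weight per cell. Ngp, Arsb, the kinase genes Stk17b (-2.46) and Mapk14, Rgs2 (-2.21), Herpud1 (-2.38), Txnip (-1.97, with -3.15 after thinning) and the apoptosis gene Pmaip1 were lower too. Pmaip1 and Mapk14 had 0 counts in the lung cells. Against a floor of 3 counts they were 3.52-fold and 3.36-fold lower, and the exact interval bounds were 2.80-fold and 2.68-fold. With the stricter cell filter the log2 ratios against the floor were -0.67 and -0.79, under 2-fold. Ngp is a neutrophil granule gene, and the other synovium cells held it at 8943 CPM. Of 8 measured neutrophil markers, 3 were at least 2-fold lower in the lung cells and 1 higher (median -0.82, -1.17 to -0.42). Whether free RNA from neutrophils plays a part was not tested. Siglecf had 3 counts in the lung cells against 53, a log2 ratio of -1.03 (-3.36 to 0.59). Itgam differed by 0.38 (-0.03 to 0.76) and Ptprc by -0.53 (-1.11 to 0.00).

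**Figure D4:**
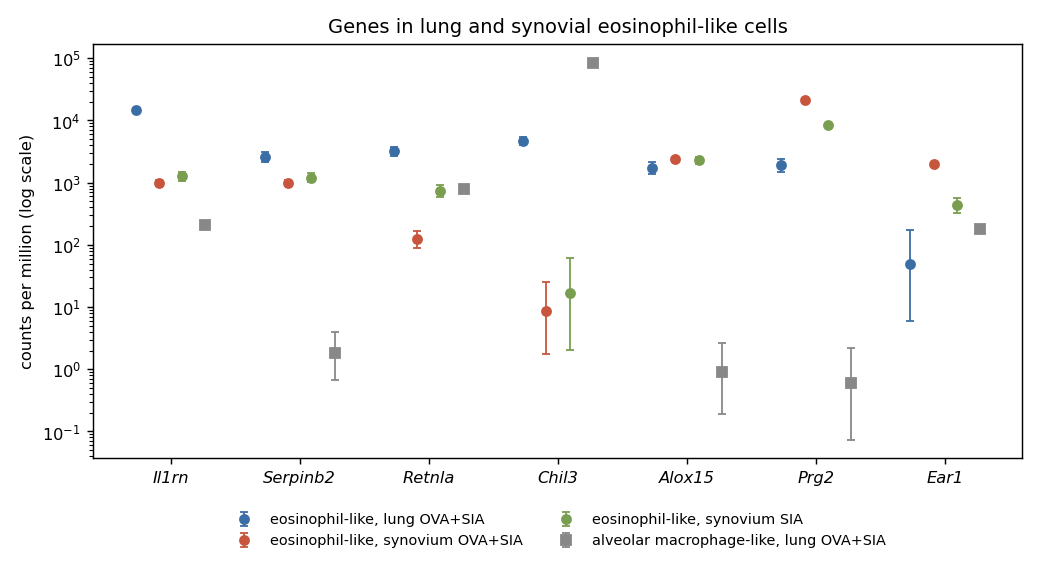
CPM on a log scale with 95% Poisson intervals for 7 genes in eosinophil-like cells of lung OVA+SIA, synovium OVA+SIA and synovium SIA, with alveolar macrophage-like lung cells for reference. Il1rn is at 14777 in lung eosinophil-like cells and 986 and 1266 in synovial ones, while Prg2 is at 1905, 21630 and 8383.

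Lists of repair, regulatory and inflammatory factors had higher medians in lung eosinophil-like cells. Macrophage genes were higher in the same cells, with 2 of 3 measured macrophage markers (median 2.56) and 2 of 2 alveolar macrophage markers (median 7.55, with Car4, not listed in the synovium, at the floor) at least 2-fold higher. Car4 stood in these lung cells at 375% of its level in the other lung cells, so it does not speak for macrophage RNA there. Eosinophil markers were at least 2-fold lower in 7 of 10 (median -2.05), 5 of these 7 being granule genes. Tissue repair and matrix factors had 9 of 14 members at least 2-fold higher and 0 lower, with a median of 1.41 (1.15 to 1.61, percentile 100). Inflammatory cytokines and chemokines had 7 of 12 higher and 1 lower (median 1.21, 0.62 to 1.40, percentile 100), with the neutrophil chemokine Cxcl2 at 5886 against 1807 CPM (1.70, 1.48 to 1.92). Regulatory and pro-resolving factors had 4 of 10 higher and 1 lower (median 0.82, 0.60 to 1.20, percentile 98.7), the 4 being Il1rn, Nr4a1, and Chil3 and Retnla, which other lung cells also carried, with Nr4a1 under 2-fold in the stricter cell filter (0.79); among members with at least 100 UMIs the median was 1.57. NF-kappaB targets had 5 of 17 higher and 1 lower (median 0.79, 0.39 to 0.99), and IL-4 and IL-13 response genes 3 of 5 higher (median 1.27). The 3 include Chil3 and Retnla again, which other lung cells also carried. Resident-type lung eosinophil markers were lower in 4 of 6 (median -1.57, -1.85 to -0.55), while Cd34 was higher (4.55, 3.24 to 6.04). The inflammatory-type markers had 4 of 10 higher, including Itgax (CD11c, 2.69) and Cd80 (1.44), and 2 lower, with a median of 0.36 (0.02 to 0.96). That median was -0.47 after thinning, -0.05 with equal weight per cell and 1.44 among members with at least 100 UMIs, so its sign depended on the setting.

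Of 11 genes listed for MHC class II presentation only 2 were measured, and the class II chain genes were not among them. Both were higher in the lung cells, the protease Ctss with 24 counts against 2 (6.69, 4.68 to 9.82) and Cd80, with a median of 4.07. Whether free RNA from other lung cells plays a part for Ctss was not tested. Among the other lists the median was 0.41 over 18 immediate early genes, 0.38 over 15 glycolysis and hypoxia genes, 0.36 over 10 genes of IL-5 signalling and 0.23 over 15 adhesion receptors, of which Itga4 was lower (-3.03) and Itgax higher. It was -0.14 over 12 cell death genes, -0.16 over 12 mitochondrially encoded transcripts, -0.38 over 9 eicosanoid genes and -0.01 over 2 interferon response genes.

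Set side by side, the eosinophil-like cells of the joints resembled each other more than either resembled those of the lung. Across 1047 genes, with each sum thinned to 40941 UMIs, the Spearman correlation was 0.718 between the joints, 0.546 between lung and synovium OVA+SIA and 0.572 between lung and synovium SIA. These are correlations across genes, which are not independent replicates. Alox15, a lipoxygenase of eosinophils, was close in the joints at 2396 CPM in synovium OVA+SIA and 2296 in synovium SIA, with 1734 in the lung. Lung OVA+SIA and synovium SIA differ in both tissue and treatment, so the Il1rn log2 ratio of 3.54 (3.28 to 3.81) and the Prg2 log2 ratio of -2.14 (-2.49 to -1.80) between them belong to neither difference alone.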

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

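Tests of clusters 3, 6 or 7 alone, of synovial eosinophil-like cells named within each library, and every value for lung eosinophil-like cells were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because each group had 1 pooled library. Between the joints, 222 values of named genes under the alternatives stayed within the counting interval of the reported value. Another 40 moved beyond it in the same direction and 1 reversed. For list medians, 193 stayed, 26 moved and 1 reversed. A list median counted as reversed only where its reported range excluded 0, so moved medians can include changes of sign. For all lung and synovium cells, 118 gene values stayed and 50 moved, and 102 list medians stayed, 50 moved and 1 reversed. For lung eosinophil-like cells, 172 gene values stayed and 20 moved, and 143 list medians stayed, 23 moved and 2 reversed. Of the shares of 6 classes in 3 libraries, 71 stayed and 19 moved. In neutrophil-like cells of the joints, single clusters left 5 list medians within range, moved 3 and reversed 3: neutrophil (-0.0154) and macrophage markers (0.48) in cluster 7 and dividing cell markers (-2.02) in cluster 6. Leiden resolution 1.0 gave no value for lung eosinophil-like cells, because it named too few of them. No cell filter, Scrublet and Leiden resolution 1.0 left the gene and list values between the joints as they were and say nothing about their stability. The cell filter removed no cell and Scrublet called 1 lung cell, so elsewhere these settings say next to nothing as well. Each gave 24 gene values and 17 list medians that stayed over all lung and synovium cells. Each gave as many in lung eosinophil-like cells, and 18 of the shares that stayed. Scaling by the median ratio moved the median of all genes by 0.14 between the joints, 0.18 over all lung and synovium cells and -0.30 in lung eosinophil-like cells. Depth limits the lung eosinophil-like cells most, where 3 counts amount to 73.3 CPM.

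Where a value moved or reversed, the cause was not tested, except that thinning and equal weight lower the say of deep cells and a minimum changes the members. Thinning also raises the level that the floor of 3 counts stands for. With the stricter cell filter the eosinophil-like shares were 49.5% in synovium OVA+SIA and 21.5% in synovium SIA, and the neutrophil-like shares 29.5% and 51.3%; the monocyte-like share was 13.98% in synovium OVA+SIA. With each library clustered alone, the eosinophil-like share of lung was 9.11%, and the neutrophil-like share 37.3% in synovium SIA and 0% in lung. The monocyte-like share was then 18.96% in lung and 0% in both synovium libraries, and lung held 15.99% alveolar macrophage-like and 28.4% macrophage-like cells. Leiden resolution 1.0 gave monocyte-like shares of 6.69% and 11.7% in synovium OVA+SIA and synovium SIA, 16.4% macrophage-like cells in lung, and dendritic cell-like shares of 4.09% in lung, 1.46% in synovium OVA+SIA and 3.47% in synovium SIA. Between the joints, all cells gave medians of 3.23 for granule proteins and 0.12 for inflammatory-type markers, a reversal. Cluster 3 alone gave 1.404 and -0.029 for these lists and -0.26 for H2afx, a reversal. Thinning gave 1.31 for granule proteins, members with at least 100 UMIs -0.59 for cytokines, and the median ratio 0.16 for regulatory factors.

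Over all lung and synovium cells, thinning gave -3.67 for granule proteins, -0.93 for resident-type markers, 1.10 for regulatory factors, -0.38 for cytokines and -0.19 for IL-5 signalling, a reversal. Equal weight per cell gave -4.63, -0.90 and 1.16 for the first 3 of these and -1.17 for inflammatory-type markers. Members with at least 100 UMIs gave -2.14 for resident-type markers, 1.34 for regulatory factors, 0.26 for cytokines and 0.41 for inflammatory-type markers. The median ratio gave -1.07 for resident-type markers and 0.66 for regulatory factors, and the trimmed total -1.14 for resident-type markers.

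In lung eosinophil-like cells, thinning gave -2.23 for granule proteins and -0.47 for inflammatory-type markers, and equal weight -2.43 and -0.0545, both reversals for the latter list. Regulatory factors had 1.52 with members of at least 1 UMI, 1.57 with at least 100 and 0.52 with the median ratio. Inflammatory-type markers had 1.44 with at least 100 UMIs. Resident-type markers had -1.87 with the median ratio and -1.98 with the 44 cells of cluster 1.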

Other observations

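The tests of the granule, Il1rn, Retnla and macrophage gene patterns, and those within single neutrophil-like clusters, were chosen only after the results were seen, except that thinning of the granule list had been planned and was read as a test of depth afterwards; the tests of the eosinophil-like share were written before.

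Interferon response genes were lower in neutrophil-like cells of synovium OVA+SIA. Of 16 measured interferon response genes, 9 were at least 2-fold lower in synovium OVA+SIA (108 cells) than in synovium SIA (169 cells) and 0 higher, with a median log2 ratio of -1.28 (-1.51 to -0.75). Rsad2, the gene of the antiviral protein viperin, stood at 73.7 against 237 CPM (-1.68, -2.22 to -1.18), and Ifit1 at 20.8 against 80.5 CPM (-1.95, -3.02 to -1.03). Inflammatory cytokines and chemokines had 5 of 14 lower and 1 higher (median -0.56, -0.76 to -0.22); Ccl3 stood at 302 against 657 CPM (-1.12, -1.38 to -0.86), while the neutrophil chemokine Cxcl1 was higher (1.32, 0.73 to 1.92). Other lists differed as well: monocyte markers were lower, 7 of 9 at least 2-fold (median -1.81, -2.36 to -1.41), as were 3 of 5 macrophage markers (median -1.09), and mitochondrially encoded transcripts had a median of -0.47 over 12 with 0 past 2-fold. Markers of dividing cells were higher in 4 of 8 (median 0.96, 0.66 to 1.08). Neutrophil markers themselves differed little, with a median of 0.23 over 14 genes and 0 past 2-fold.

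The neutrophil-like class was mixed differently in the joints. Cluster 7, led by Hcar2, Nlrp3 and Tnf among others, gave 35 of 108 cells in synovium OVA+SIA and 89 of 169 in synovium SIA; cluster 6, led by Mmp8 and Lcn2 among others, gave 60 and 67, and cluster 10, led by Camp, Ngp and Rrm2 among others, 13 and 13. The interferon median was -1.30 (-1.75 to -0.73) within cluster 7 and -0.65 (-1.11 to -0.15) within cluster 6. The cytokine median was -0.37 (-0.65 to 0.08) within cluster 7 and -0.0242 (-0.26 to 0.23) within cluster 6. Monocyte markers were lower within both (-1.52 and -1.72), while macrophage markers were lower within cluster 6 (-1.40) and not within cluster 7 (0.48, -0.26 to 1.17). The median of dividing cell markers was -2.02 over 3 genes within cluster 6. Whether the interferon difference is tied to that in monocyte markers was not tested. Thinning, equal weight per cell and the stricter cell filter were not tried for the list medians of neutrophil-like cells.

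Granule protein transcripts were higher in eosinophil-like cells of synovium OVA+SIA than of synovium SIA. Free RNA is argued against, since the excess in neutrophil-like cells (92.6 against 73.5 CPM over the list) was 0.111% of that in eosinophil-like cells (27007 against 9784 CPM). Unequal depth as the whole cause is argued against, since the thinned list median was 1.31 (0.86 to 1.79), although 3 of 6 members were then at least 2-fold higher, against 5 before. Carry-over of bone marrow cells stays open: the odds ratio of eosinophil-like cells with an Epx UMI (36 and 7) to precursor cells of clusters 8 and 10 (26 and 20) was 3.89, but it rests on cells of 1 library per group and on a gene of the pattern itself. The mix of clusters differed too: cluster 9, led by the granule genes, gave 100 and 14 cells, and cluster 3 gave 190 and 89. Within cluster 3 alone Prg2, Ear1, Ear2 and Ear6 were still higher, but by less than over the class. Since granule genes lead cluster 9, this cannot tell more such cells from more transcript per cell. A larger share of young eosinophils in mice with asthma and a difference between pools of mice stay open as well and were not tested.

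Il1rn, Retnla, Chil3, Psap and Ctsb were higher in lung than in synovial eosinophil-like cells of mice with OVA+SIA. For Il1rn, free RNA is argued against, since its level was 10.9 times that of the highest other lung cluster of at least 10 cells (1353 CPM). For Retnla the matter stays open, since its level was 1.16 times that of the highest other lung cluster (2749 CPM). For Chil3, Psap and Ctsb free RNA from macrophages is a candidate source, since they stood at a median of 13.9% of their level in the other lung cells. Chil3, with 192 counts, stood lower at 9.20%, while Psap stood at 14.0% and Ctsb at 13.9%. Of 15 macrophage and alveolar macrophage markers, 13 matched that median within counting error, with Apoe and Car4 as exceptions. Few counts lay behind most markers, and C1qa, C1qb, C1qc, Fabp4 and Plet1 had 0, so they could hardly differ from it. The tissue difference itself, the airway against the joint, remains a candidate explanation for Il1rn.

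The eosinophil-like share was higher in synovium OVA+SIA than in synovium SIA. Granule genes driving the grouping of cells are argued against, since clustering without them gave 60.9% (56.3 to 65.3%) against 27.5% (23.0 to 32.3%). Their part in the naming stays open, since the clusters were still named with them. Loss of cells below the UMI floor stays open: the share of eosinophil-like cells under 1000 UMIs differed by -0.666 percentage points (57.6% against 58.3%), but cells below the floor were not seen. Among cells with at least 1000 UMIs the eosinophil-like share was 42.0% against 14.6%. More eosinophils reaching the joint in mice with asthma may account for the difference, but with 1 pooled library per group a difference between pools stays open as well. A share of the sorted gate also cannot tell more eosinophil-like cells from fewer other cells.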
